A study of Homo sapiens with 18 samples.

How the data were processed

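RNA was sequenced from LNCaP cells, an androgen-responsive human prostate cancer line, in 18 libraries that form 6 groups of 3 (biological triplicates, per the labels' protocols). Cells received a pool of siRNAs (SmartPool) against UPF1, against RCOR1, or a non-targeting control pool. UPF1 is the RNA helicase at the core of nonsense-mediated decay (NMD), the pathway that degrades transcripts with premature stop codons. RCOR1 (CoREST) is the scaffold that holds the histone demethylase KDM1A and histone deacetylases in a repressor complex. Medium without androgen was given from the day after transfection. At 48 h after transfection, R1881, a synthetic androgen, was added at 5 nM, or ethanol as vehicle, and cells were collected after 48 h of treatment. Libraries were made from 500 ng of total RNA after depletion of ribosomal RNA, so that unspliced and non-polyadenylated RNA contributed to the counts.

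The deposited values were raw counts, whole numbers of reads per gene and library, with no normalization. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20, aligned with STAR 2.7.9a to the human genome build GRCh38.p7, and counted with featureCounts of Subread 1.6.4. The gene annotation release, the strand setting and any read filters are not given in the sources used here. Reads shared between gene copies are therefore of uncertain assignment in the replication-dependent histone genes, UGT2B17 and UGT2B15, KLK2 and KLK3, and ribosomal protein and mitochondrial genes that have pseudogenes. The same holds for antisense RNAs such as TPM1-AS, which may hold reads of the opposite strand. The file held 60649 genes, of which 140 symbols were used by more than 1 gene; genes were therefore followed by identifier. Totals per library lay between 10299607 and 17338235 counts. All 18 libraries were used.

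Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 15390 genes. Libraries were scaled by trimmed mean of M values (TMM). A negative binomial model with 1 mean per group was fitted to all 18 libraries, and contrasts were tested with edgeR's quasi-likelihood F test. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. The common dispersion was 0.024. Values are log2 fold changes ± standard error (SE) or CPM (TMM-scaled) with standard deviations (SD) over 3 libraries. The SE was derived from the test, as the absolute log2 fold change divided by the square root of F. A fold change against a group with 0 counts in every library is given against a floor of 3 counts over the group, with a lower 95% counting limit. SE cover the counting error and the spread between libraries, and floors and counting limits cover counting error only. None covers the spread between other siRNAs, since each gene was targeted with 1 pool.

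The 9 contrasts were the response to R1881 within each of the 3 siRNA arms, each targeting siRNA against control siRNA in vehicle and in R1881, and the 2 interactions. An interaction is the R1881 response with the targeting siRNA minus the R1881 response with control siRNA. The size of the androgen response was compared over genes called with an absolute log2 fold change of at least 1 in the arm not compared, by the median response signed by direction in that arm and by the regression slope through the origin. The overlap between the calls of the 2 siRNAs in vehicle was set beside the count that independent lists would share and beside simulated groups that share the same controls.

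The 18 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and contrasts. Of the 162 combinations, 72 were called, and 27 of them were called with a correlation estimated from the data. The lists were androgen-induced genes, androgen-repressed genes, luminal prostate genes, S phase and mitosis genes, NMD factors other than UPF1, NMD targets, replication-dependent histone genes, targets of the integrated stress response (ATF4 targets), chaperones and secretory genes of the endoplasmic reticulum (ER), neuronal genes repressed by REST, members and partners of the CoREST complex, markers of epithelial-mesenchymal transition (EMT), sterol and fatty acid synthesis genes, interferon-stimulated genes, p53 targets, mitochondrially encoded genes, ribosomal protein genes, and markers of other cell types. Listed genes that the low-count filter removed were not tested. This left 18 of 41 REST-repressed neuronal genes, 49 of 83 histone genes, 6 of 14 EMT markers and 6 of 20 markers of other cell types. Members called are counted both over all genes and adjusted over the list alone. The histone list, taken by symbol pattern, also took in 5 genes that are no replication-dependent histone genes: H1-10, its antisense gene H1-10-AS1 and the pseudogenes H1-12P, H2BC19P and H2BC20P. Some genes stand in more than 1 list, such as ATF3, ATF4, CDKN1A, KLK3, SNAI1 and SPDEF.

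The contrasts, tests, lists, rules for naming genes and most alternative settings were set before the data were examined. Named genes were UPF1 and RCOR1, the 8 highest and 8 lowest log2 fold changes in the androgen response with control siRNA and in each siRNA comparison in vehicle, the 6 highest and 6 lowest in each interaction, up to 4 members per list with the smallest adjusted p, and KLK3, TMPRSS2, FKBP5 and GAS5. Some genes that these rules select are not reported here. The genes ranked by fold change had to be called and to have a mean log2 CPM of at least 2, and in the simple comparisons all 3 libraries of one group had to lie above all 3 of the other. List members that moved against the rest of their list, and genes behind counts of 5 or fewer, are named as well; these were chosen after their values were seen.

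The settings varied were size factors of DESeq2 (relative log expression, RLE), library size alone, no low-count filter, a filter at 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, a fit of only the groups compared, 1 surrogate variable from sva 3.50.0, the rotation test fry, an estimated correlation, another choice of genes for the size of the androgen response, and leaving out each library in turn. After the data were seen, an offset for GC content and transcript length was added (a spline with 4 degrees of freedom, fitted per library), with properties from GENCODE release 29 for 15203 of the tested genes, 98.8%. Runs without 2 libraries in doubt from the group with UPF1 siRNA and R1881, runs without 2 control libraries, and the surrogate variable for lists, sizes and overlap were also added then, as were the order of the titles as a block, the simulation of unchanged arms for the interactions and the slopes with control libraries set against each other. The fit was tested on simulated counts with known changes, drawn from the means, library sizes and dispersions of the real data. The draws used 1 mean per gene for all libraries and lacked the differences between libraries in AT-rich genes. Recovery in the real libraries may therefore differ. Of genes changed 2-fold, it recovered 73.1% for the androgen response with control siRNA and 41.8% for the UPF1 interaction. In these draws the interactions thus had less power than the simple comparisons. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.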

Results

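The transcriptome of LNCaP cells was measured by sequencing of ribosomal RNA-depleted total RNA in 18 libraries, 3 for each combination of siRNA (control, UPF1 or RCOR1) and treatment (vehicle or 5 nM R1881). The question set by the design was how much UPF1 and RCOR1 contribute to the androgen response of these cells. The totals per library ran from 10299607 to 17338235 counts. With control siRNA they were 14402924, 13402618 and 10299607 in vehicle. In R1881 they were 14904489, 15479748 and 12650267. With UPF1 siRNA they were 14175496, 12230888 and 13748205 in vehicle and 17338235, 14494982 and 12499252 in R1881. With RCOR1 siRNA they were 14242458, 13097351 and 11950288 in vehicle and 13744437, 12181389 and 13236955 in R1881. The first principal component held 44.2% of the variance and the second 20.9%. Libraries of one group also differed in the share of AT-rich transcripts. The long nuclear RNA MALAT1 ranged from 3761 to 35087 CPM over the 18 libraries, and the first component of the within-group differences held 41.2% of their variance and followed GC content across genes (Spearman rho 0.88). Replicates 1 and 2 of the group with UPF1 siRNA and R1881 had the lowest levels of genes with a GC content below 40%, with median deviations of -0.66 and -0.43 log2 CPM from the mean of all libraries.

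**Figure D1:**
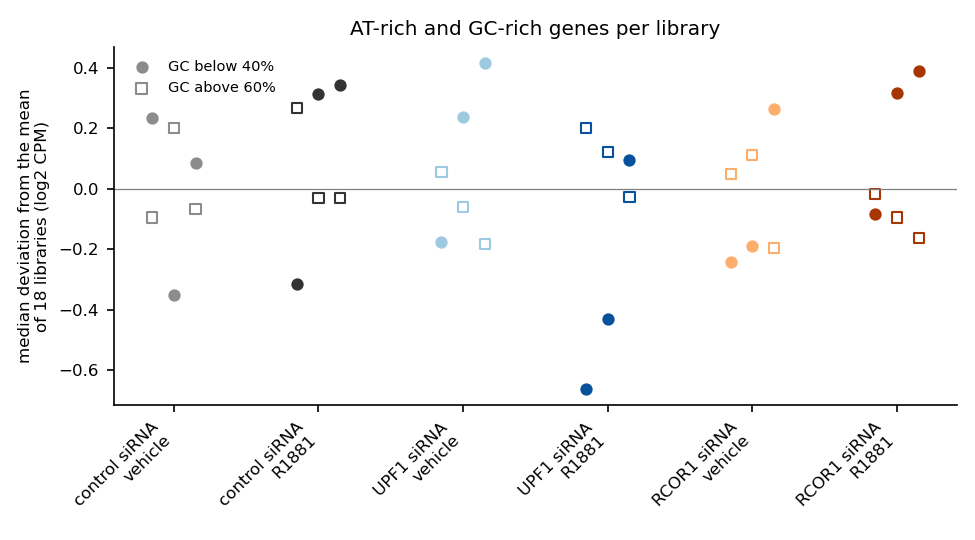
Each point is the median deviation, in log2 CPM from the mean of the 18 libraries, of the 1805 genes with a GC content below 40% (filled circles) or the 1407 genes above 60% (open squares) in 1 library, by group. The AT-rich genes of replicates 1 and 2 with UPF1 siRNA and R1881 lie lowest, at -0.66 and -0.43.

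Both siRNA pools lowered their target transcripts in every library. UPF1 (ENSG00000005007.13, GRCh38 chromosome 19, 18831938 to 18868236) stood at 22.8 ± 2.8 CPM (SD, n = 3) with its siRNA in vehicle against 134 ± 18 CPM with control siRNA, 17% of the control level. In R1881 it stood at 26.3 ± 0.67 against 149 ± 13 CPM, 17.6% of control. RCOR1 (ENSG00000089902.10, chromosome 14, 102592661 to 102730576) stood at 12.8 ± 3.4 against 99.6 ± 8.8 CPM in vehicle, 12.9% of control, and at 12.5 ± 0.3 against 79.7 ± 10 CPM in R1881, 15.7% of control. The log2 fold changes of UPF1 were -2.56 ± 0.12 (SE, edgeR adjusted p = 1.1e-09) in vehicle and -2.51 ± 0.11 (edgeR adjusted p = 1.2e-09) in R1881. Those of RCOR1 were -2.95 ± 0.15 (edgeR adjusted p = 1.9e-08) and -2.67 ± 0.15 (edgeR adjusted p = 6.6e-08). UPF1 was also lower with RCOR1 siRNA in R1881, by a log2 fold change of -0.36 (edgeR adjusted p = 0.04), with -0.32 in vehicle (edgeR adjusted p = 0.067). RCOR1 with UPF1 siRNA changed by -0.22 in vehicle and 0.16 in R1881, neither of which was called by edgeR (adjusted p = 0.24 and 0.42). Protein levels were not analysed here.

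**Figure D2:**
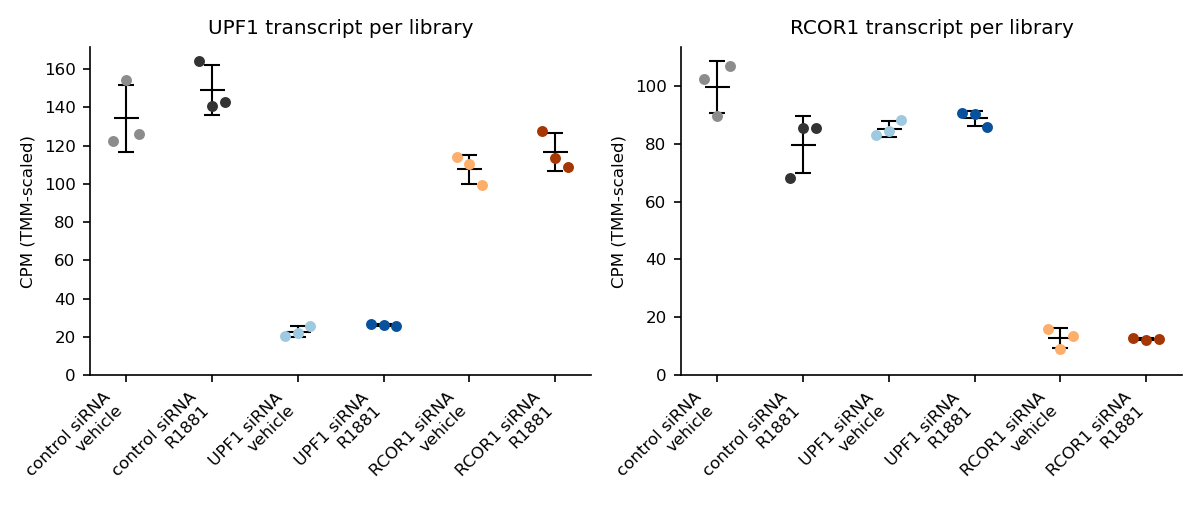
Points are CPM (TMM-scaled, linear axis) of UPF1 and of RCOR1 in each of the 18 libraries by group; horizontal bars are the group mean and 1 SD over 3 libraries. Each target lies lowest in the 6 libraries with its own siRNA, at 20.5 to 26.8 CPM for UPF1 and 9.1 to 15.8 CPM for RCOR1.

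The androgen response with control siRNA shows what R1881 does in these cells. Classic androgen-induced genes rose steeply: KLK3 (chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, from 296 ± 47 to 3620 ± 340 CPM, the protease gene TMPRSS2 from 214 ± 22 to 2330 ± 96 CPM, and FKBP5, a co-chaperone of steroid receptors, from 59.4 ± 3.6 to 2200 ± 340 CPM. STEAP4 (chromosome 7, 88270892 to 88306891), a metalloreductase, had 0 counts in the 3 vehicle libraries and 4359 in the 3 R1881 libraries. Against a floor of 3 counts over the group it was 1520-fold higher, with a lower 95% counting limit of 1240-fold. Among the other steepest rises were the muscle protein gene TTN (log2 fold change 7.15 ± 0.52), the nicotinic receptor subunit CHRNA2 (6.27 ± 0.17), MYBPC1 (5.74 ± 0.41), the coagulation factor F5 (5.26 ± 0.26), FKBP5 (5.21 ± 0.13), the pseudogene ZNF812P (5.01 ± 0.18) and KLK2 (4.89 ± 0.11). The steepest falls were in SLITRK3, a neuronal adhesion protein (-5.40 ± 0.16), the kappa opioid receptor OPRK1 (-4.16 ± 0.087), the death-associated kinase DAPK1 (-3.94 ± 0.22), the chemokine receptor ACKR3 (-3.94 ± 0.12), the androgen-inactivating enzyme UGT2B17 (-3.89 ± 0.14), butyrylcholinesterase BCHE (-3.84 ± 0.36), the interleukin-1 receptor antagonist IL1RN (-3.78 ± 0.17) and the collagen gene COL5A2 (-3.61 ± 0.15).

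By list, 40 of 41 androgen-induced genes rose, with a median log2 fold change of 3.15, which held with STEAP4 set at the floor of 3 counts (40 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.4e-38). MED28 was the exception at -0.21. Of 13 androgen-repressed genes, 12 fell and UGT2B11 rose by 2.96 (median -3.31; 12 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.2e-10). S phase and mitosis genes fell in 34 of 35 cases (34 adjusted over the list alone, median -1.45, camera adjusted p = 3.2e-19). With an estimated correlation this list had adjusted p = 0.069. Its members included the spindle factor TPX2 (-1.70), the replication helicase subunit MCM4 (-1.45), thymidylate synthase TYMS (-1.82) and the mitotic kinase PLK1 (-1.83). The list of replication-dependent histone genes fell in 40 of 49 cases while H2BC21 rose, as did H1-10, a replication-independent linker histone that the symbol pattern of the list took in (median -1.54; 40 lower and 2 higher adjusted over the list alone, camera adjusted p = 7e-16). This changed to adjusted p = 0.17 with an estimated correlation. ER chaperone and secretory genes rose in 22 of 24 cases, with the stress sensor ERN1 at 1.87, the coat protein SEC24D at 2.2 and the transcription factor XBP1 at 1.35 (median 1.05; 24 higher adjusted over the list alone, camera adjusted p = 9.8e-15). Sterol and fatty acid synthesis genes rose in 23 of 27 cases, with INSIG1 at 1.86, while ELOVL6 and TM7SF2 fell (median 0.91; 23 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.5e-11).

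Smaller shifts followed in other lists of the androgen response. Integrated stress genes rose in 14 and fell in 4 of 28 cases, with ATF3 at 1.52 and NUPR1 at 0.94 and with SLC7A5, SESN2, PHGDH and ALDH1L2 lower (18 higher and 5 lower adjusted over the list alone, median 0.36, camera adjusted p = 0.0092). That list had adjusted p = 0.34 with an estimated correlation. The p53 targets fell in 11 of 22 cases, among them BTG2 (-1.75) and SESN1 (-1.6), while TNFRSF10B (1.6) and GDF15 (1.70) rose (11 lower and 2 higher adjusted over the list alone, median -0.38, camera adjusted p = 0.0035). Luminal genes rose in 8 and fell in 3 of 16 cases (9 and 4 adjusted over the list alone, median 0.29, camera adjusted p = 0.019, and adjusted p = 0.071 with an estimated correlation); keratin KRT18 rose by 2.02, and GATA2 and FOLH1 were among those that fell. Mitochondrially encoded genes rose in 8 of 13 cases (8 adjusted over the list alone), with MT-CYB at 0.42 (median 0.32, camera adjusted p = 0.016). The call was lost at adjusted p = 0.57 with an estimated correlation. The lists of NMD factors (median 0.19), NMD targets (0.02), REST-repressed neuronal genes (0.07), CoREST members (-0.13), EMT markers (0.01), interferon-stimulated genes (0.06, where the test pointed down), ribosomal protein genes (0.04) and markers of other cell types (-0.07) were not called by camera (adjusted p = 0.35, 0.49, 0.92, 0.19, 0.91, 0.97, 0.49 and 0.91). With library size alone as scaling, the medians of all of these but CoREST members and other cell types turned from positive to negative, -0.20 for ribosomal protein genes. Single members still moved, such as the EMT factor SNAI2 (4.64), the neuropeptide precursor VGF (2.72), the NMD factor SMG5 (0.64) and the corepressor CTBP1 (-1.28), while the host gene GAS5 was at -0.05 (edgeR adjusted p = 0.71). In all, edgeR called 5801 of 15390 genes, 3090 higher and 2711 lower; 917 rose and 1206 fell at least 2-fold. With library size alone the median of all genes moved by -0.22, and 26.5% of calls were higher instead of 53.3%.

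**Figure D3:**
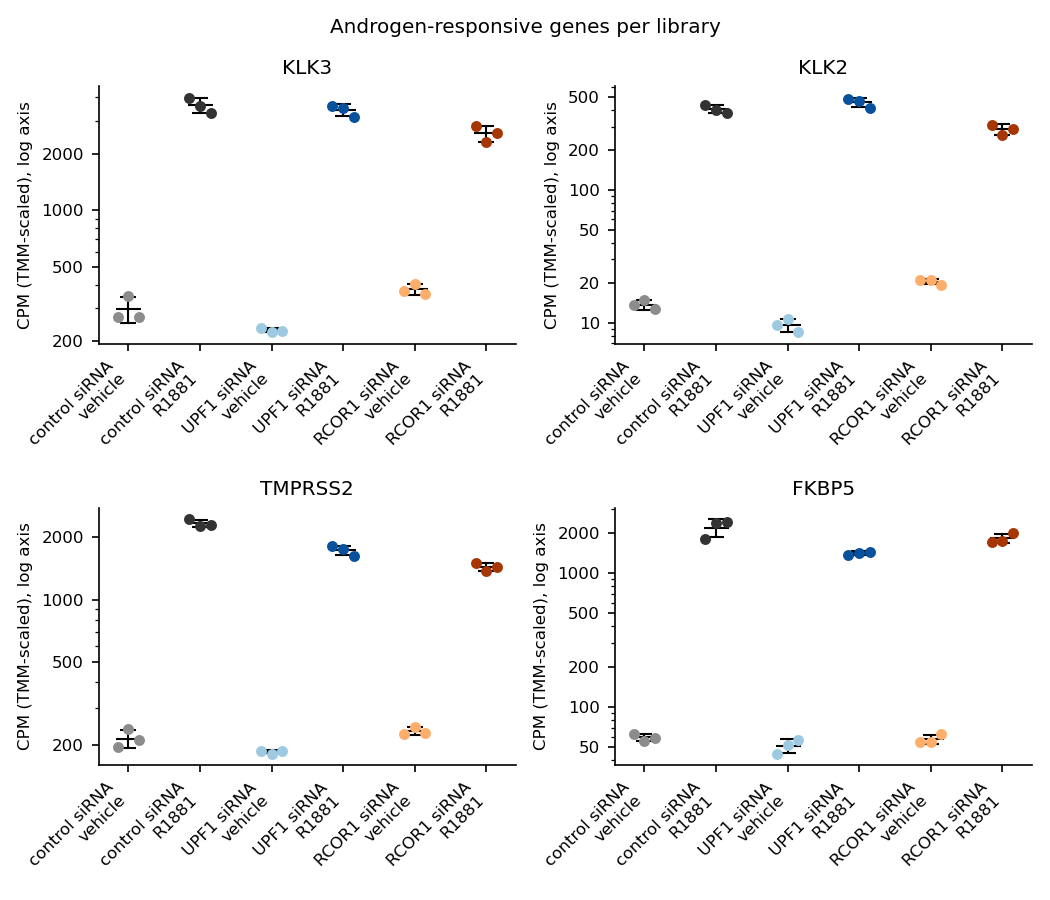
Points are CPM (TMM-scaled, log axis) of 4 genes in each of the 18 libraries by group; horizontal bars are the group mean and 1 SD over 3 libraries. KLK3, KLK2, TMPRSS2 and FKBP5 are higher in R1881 in each siRNA arm.

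The androgen response was kept in both targeted arms. With UPF1 siRNA, KLK3 rose from 230 ± 5.5 to 3410 ± 250 CPM, TMPRSS2 from 185 ± 3.1 to 1730 ± 89 CPM and FKBP5 from 51.3 ± 6.1 to 1410 ± 43 CPM. With RCOR1 siRNA, KLK3 rose from 378 ± 26 to 2570 ± 250 CPM, TMPRSS2 from 232 ± 11 to 1440 ± 65 CPM and FKBP5 from 57.5 ± 4.5 to 1820 ± 150 CPM. Of the 41 androgen-induced genes, 39 rose in each arm (39 in each adjusted over the list alone, and 1 lower with UPF1 siRNA), with medians of 2.66 with UPF1 siRNA and 2.82 with RCOR1 siRNA (camera adjusted p = 1.7e-35 and 1.6e-41). Of the 13 androgen-repressed genes, 12 fell in each arm and UGT2B11 rose (12 lower and 1 higher adjusted over the list alone in each), with medians of -2.98 and -2.83 (camera adjusted p = 6.6e-11 and 4.7e-11). S phase and mitosis genes fell in 27 and 29 of 35 cases (29 and 32 adjusted over the list alone), with medians of -1.27 and -0.99 (camera adjusted p = 1.6e-11 and 9.8e-15, and adjusted p = 0.17 and 0.11 with an estimated correlation). The count over all genes was 6405 with UPF1 siRNA (3321 higher, 3084 lower) and 4796 with RCOR1 siRNA (2508 higher, 2288 lower), and 1710 genes rose and 1323 fell in all 3 arms. Opposite directions were called for 34 genes with control and UPF1 siRNA, KLF4 among them, and for TGFBR3, HOXB9 and AMOT with control and RCOR1 siRNA. With library size alone the share of higher calls was 37.3% instead of 51.9% with UPF1 siRNA and 29.3% instead of 52.3% with RCOR1 siRNA. Without replicates 1 and 2 of the group with UPF1 siRNA and R1881, the count with UPF1 siRNA was 2924.

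With either siRNA the slope of the response against that with control siRNA lay below 1, while the median depended for UPF1 siRNA on the choice of genes. Over 1595 genes chosen in the RCOR1 arm, the median response was 1.61 log2 units with control siRNA and 1.41 with UPF1 siRNA, the slope was 0.828, and 63% of genes responded less. Over 2352 genes chosen in the UPF1 arm, the median response was 1.22 with control siRNA and 0.96 with RCOR1 siRNA, the slope was 0.822, and 66.1% of genes responded less. Over genes called in either of the arms compared, the median with UPF1 siRNA was the larger one, 1.335 against 1.259 with control siRNA, and 48.6% of 3179 genes responded less, with a slope of 0.82. With RCOR1 siRNA the median over such genes was again lower, 1.226 against 1.441. On log2 CPM with a prior count of 2, a scale other than that of the fitted values above, slopes of single R1881 libraries lay between 0.846 and 0.884 with UPF1 siRNA and between 0.822 and 0.857 with RCOR1 siRNA. To give a control value from other libraries, 1 vehicle and 1 R1881 control library were set against the other control libraries in all 9 ways, which share libraries. The control slopes were 0.878 to 1.001 over the first set of genes, against 0.813 to 0.873 with UPF1 siRNA on the same axes, and 0.876 to 0.98 over the second, against 0.789 to 0.832 with RCOR1 siRNA. Genes are not independent replicates, so no p is given over genes.

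**Figure D4:**
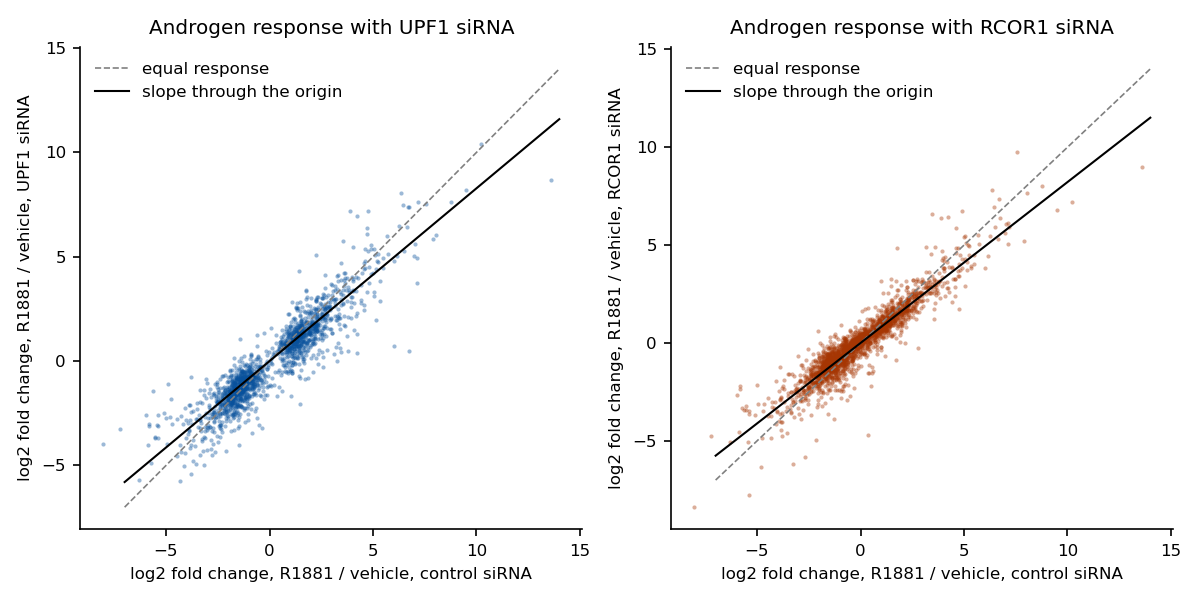
Each point is 1 gene called with an absolute log2 fold change of at least 1 in the arm not shown; the axes are its log2 fold change for R1881 against vehicle with control siRNA and with the targeting siRNA. The solid slopes through the origin, 0.828 for UPF1 siRNA and 0.822 for RCOR1 siRNA, lie below the dashed line of equal response.

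UPF1 siRNA in vehicle shows what this siRNA pool changed without androgen. With 1 pool, effects of the loss of UPF1 and other effects of the siRNAs cannot be told apart. Genes that rose most included the neuronal navigator NAV3 (3.19 ± 0.24), the NKG2D ligand RAET1L (3.07 ± 0.19), the tight junction gene CLDN8 (3.04 ± 0.19), fibrillin FBN1 (2.92 ± 0.19), the disulfide isomerase AGR2 (2.89 ± 0.11), the apoptosis inhibitor BIRC3 (2.87 ± 0.45) and the long noncoding RNA LINC00511 (2.75 ± 0.26). STEAP4 ranked with them by its fitted value, with 12 counts in 3 libraries against 0 in the controls. Against the floor of 3 counts it was 3.88-fold higher, a log2 value of 1.95, with a lower 95% counting limit of 2.69-fold. Its rank is therefore not settled. Besides UPF1, those that fell steeply included the histone genes H1-5 (-2.28 ± 0.26), H3C13 (-2.28 ± 0.23), H2BC14 (-2.24 ± 0.2) and H2AC14 (-2.17 ± 0.24), the mitotic kinesin KIFC1 (-2.27 ± 0.19) and separase ESPL1 (-2.16 ± 0.2). S phase and mitosis genes fell in 33 of 35 cases, with MCM3 at -1.51 and the transcription factor FOXM1 at -1.71 (34 adjusted over the list alone, median -1.51, camera adjusted p = 8e-23). Replication-dependent histone genes fell in 43 of 49 cases (44 adjusted over the list alone, median -1.49, camera adjusted p = 2.9e-25). The same list gave adjusted p = 0.078 with an estimated correlation. Interferon-stimulated genes rose in 20 of 23 cases, among them RSAD2 (2.72 ± 0.13), OASL (2.01), OAS2 (1.64) and IFIT1 (1.49), all antiviral effectors (22 adjusted over the list alone, median 1.24, camera adjusted p = 1.7e-11). Ribosomal protein genes fell by little but in 74 of 85 cases, while RPS27L rose (77 lower and 1 higher adjusted over the list alone, median -0.40, camera adjusted p = 1.1e-17). These genes had adjusted p = 0.3 with an estimated correlation.

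The NMD machinery and its known targets moved unevenly with UPF1 siRNA in vehicle. Of 9 other NMD factors, UPF3A (0.84), SMG9 (0.94), SMG5 (0.66), UPF3B (1.14) and SMG1 (1.21) rose and SMG8 (-0.89) fell (5 higher and 1 lower adjusted over the list alone, median 0.82, camera adjusted p = 0.045). This list had adjusted p = 0.12 with an estimated correlation. Of 35 NMD targets, 11 rose and 11 fell (13 and 11 adjusted over the list alone), with a median of 0.05 and a test pointing down (camera adjusted p = 0.97). The stress factors ATF3 (1.03) and ATF4 (0.84) rose, the snoRNA host genes SNHG16 (-1.14) and SNHG1 (-0.88) fell, and the host gene GAS5 was at 0.02 (edgeR adjusted p = 0.9). Integrated stress genes rose in 11 of 28 cases, with DDIT3 at 1.52 and NUPR1 at 1.55, and DDIT4 fell (11 and 1 adjusted over the list alone, median 0.21, camera adjusted p = 0.011). This changed to adjusted p = 0.34 with an estimated correlation. ER chaperone and secretory genes rose in 12 of 24 cases, while CANX (-1.30) and CREB3L4 (-1.01) fell (13 and 2 adjusted over the list alone, median 0.27, camera adjusted p = 0.002). That list had adjusted p = 0.11 with an estimated correlation. Sterol and fatty acid synthesis genes fell in 10 of 27 cases, with fatty acid synthase FASN at -1.15 and the desaturase FADS2 at -1.16, while SC5D and MVD rose (11 lower and 2 higher adjusted over the list alone, median -0.22, camera adjusted p = 0.028). The call was lost at adjusted p = 0.28 with an estimated correlation.

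Some androgen-induced genes differed with UPF1 siRNA before any androgen was given, with small falls of KLK3 (-0.37, edgeR adjusted p = 0.013) and TMPRSS2 (-0.21, edgeR adjusted p = 0.031). FKBP5 was at -0.21 (edgeR adjusted p = 0.16). The lists of androgen-induced genes (median 0.01, mean 0.20, with a test pointing down), androgen-repressed genes (median 0.73), luminal genes (-0.02), REST-repressed neuronal genes (0.35), CoREST members (-0.16), EMT markers (-0.70), p53 targets (0.15), mitochondrially encoded genes (-0.09) and other cell types (0.55) were not called by camera (adjusted p = 0.54, 0.075, 0.58, 0.1, 0.17, 0.19, 0.31, 0.18 and 0.11). Single members included the synaptic vesicle gene SYP (2.24), the demethylase KDM1A (-0.76), vimentin VIM (-1.0), the stress cytokine GDF15 (2.24), MT-CO2 (-0.34) and the endothelial marker VWF (1.15). In total, edgeR called 5318 genes, 2853 higher and 2465 lower, of which 667 rose and 556 fell at least 2-fold.

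In R1881, UPF1 siRNA moved many of the same genes. The relation of its log2 fold changes to GC content across genes turned, however, with a Spearman rho of -0.196 in vehicle and 0.277 in R1881. RSAD2 (1.82), OASL (1.71), NAV3 (2.87), SYP (1.98) and DDIT3 (1.25) were again higher, and H1-5 (-2.48) and FASN (-1.30) lower. Among androgen targets, TMPRSS2 (-0.43, edgeR adjusted p = 2.7e-04) and FKBP5 (-0.64, edgeR adjusted p = 3.6e-04) were lower, as was the stress-responsive gene NDRG1 (-1.33). KLK3 (-0.09) and KLK2 (0.17) were not called by edgeR (adjusted p = 0.55 and 0.16). The androgen-repressed genes OPRK1 (2.21), DDC (1.80), CAMK2N1 (1.31) and UGT2B17 (1.28) were higher. Of the 41 androgen-induced genes, 18 fell and 6 rose (20 and 6 adjusted over the list alone, median -0.22, camera adjusted p = 0.0054). S phase and mitosis genes fell in 29 of 35 cases with MCM7 higher (31 and 1 adjusted over the list alone, median -1.31, camera adjusted p = 1.6e-15, and adjusted p = 0.1 with an estimated correlation), and interferon-stimulated genes rose in 16 of 23 cases (16 adjusted over the list alone, median 0.72, camera adjusted p = 4.8e-08). Mitochondrially encoded genes fell in 8 of 13 cases (11 adjusted over the list alone, median -0.30, camera adjusted p = 7.3e-04, and adjusted p = 0.43 with an estimated correlation); with the GC and length offset the list was no longer called (camera adjusted p = 0.14) and MT-ND4L turned to 0.22. REST-repressed neuronal genes rose in 8 of 18 cases and UNC13A fell (8 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 0.02). The same list gave adjusted p = 0.071 with an estimated correlation. Genes called numbered 5128, 2710 higher and 2418 lower, and 1747 rose and 1311 fell in both treatments; 52 were called in opposite directions. Without replicates 1 and 2 of the group with UPF1 siRNA and R1881 the count was 1904, and with library size alone 67.1% of calls were higher instead of 52.8%.

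RCOR1 siRNA in vehicle changed fewer genes. The largest rises were in FAM184B (2.29 ± 0.21), heme oxygenase HMOX1 (1.80 ± 0.26), the keratin KRT19 (1.78 ± 0.18), EPDR1 (1.78 ± 0.19), fibrillin FBN1 (1.63 ± 0.21), CRISP3 (1.57 ± 0.35), the membrane scaffold EPB41L3 (1.52 ± 0.22) and the ephrin EFNA5 (1.47 ± 0.051). Besides RCOR1, the largest falls were in ZNF812P (-1.82 ± 0.26), the lysine methyltransferase SETD7 (-1.53 ± 0.17), RAB15 (-1.44 ± 0.11), SHCBP1 (-1.37 ± 0.24), GPR137C (-1.34 ± 0.29), the aromatic amino acid decarboxylase DDC (-1.28 ± 0.12) and the mitochondrial folate enzyme MTHFD2 (-1.25 ± 0.11). KLK3 rose slightly (0.35, edgeR adjusted p = 0.041), while TMPRSS2 (0.12) and FKBP5 (-0.05) were not called. S phase and mitosis genes fell in 27 of 35 cases, with the mitotic kinase AURKA at -0.95 (32 adjusted over the list alone, median -0.82, camera adjusted p = 1.5e-21). These genes had adjusted p = 0.054 with an estimated correlation. Replication-dependent histone genes fell in 21 of 49 cases (35 lower and 1 higher adjusted over the list alone, median -0.49, camera adjusted p = 8.4e-11). This list had adjusted p = 0.28 with an estimated correlation. Integrated stress genes fell in 11 of 28 cases, with the serine synthesis enzyme PSAT1 at -0.78, while DDIT3 rose (16 lower and 2 higher adjusted over the list alone, median -0.28, camera adjusted p = 9e-07). This changed to adjusted p = 0.077 with an estimated correlation. ER chaperone and secretory genes fell in 6 of 24 cases (11 adjusted over the list alone, median -0.18, camera adjusted p = 1.4e-04, and adjusted p = 0.062 with an estimated correlation), and sterol and fatty acid synthesis genes in 9 of 27 cases, with the desaturase SCD at -0.60 (11 adjusted over the list alone, median -0.23, camera adjusted p = 8.2e-06). Androgen-repressed genes fell in 5 of 13 cases, with UGT2B17 at -1.09, while CAMK2N1 rose (9 lower and 1 higher adjusted over the list alone, median -0.74, camera adjusted p = 0.0013). That list had adjusted p = 0.29 with an estimated correlation.

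Of 41 listed neuronal genes that REST and CoREST repress, 18 passed the low-count filter, and the others were not tested. These 18 did not rise as a group with RCOR1 siRNA in vehicle: the neurofilament NEFL (0.70) rose and STMN3 (-0.87) and DPYSL3 (-0.58) fell (1 higher and 2 lower adjusted over the list alone, median -0.10, camera adjusted p = 0.52). Interferon-stimulated genes RSAD2 (0.55), IFIT1, STAT2 and IFIT3 rose among 23 (6 higher adjusted over the list alone, median 0.30, camera adjusted p = 0.017). The call was lost at adjusted p = 0.34 with an estimated correlation. Ribosomal protein genes RPS4X, RPS27, RPS12 and RPS25 rose and RPL7L1 fell among 85 (none adjusted over the list alone, median 0.13, camera adjusted p = 1.3e-05). The same list gave adjusted p = 0.59 with an estimated correlation. The lists of androgen-induced genes (0.11), luminal genes (-0.06), NMD factors (-0.10), NMD targets (-0.05), CoREST members (-0.02, and 0.01 with library size alone), EMT markers (0), p53 targets (-0.07), mitochondrially encoded genes (0.09) and other cell types (0.18, with a mean of -0.01) were not called by camera (adjusted p = 0.061, 0.25, 0.85, 0.97, 0.9, 0.79, 0.97, 0.21 and 0.89). GAS5 stood at 0.28 (edgeR adjusted p = 0.05). In all, edgeR called 1772 genes, 817 higher and 955 lower, of which 179 rose and 98 fell at least 2-fold. The count fell to 1153 without siRCOR1 replicate 1 in vehicle and to 1118 without replicate 2, and was 2855 with 1 surrogate variable and 3639 with the GC and length offset.

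In R1881, RCOR1 siRNA lowered a set of androgen targets: TMPRSS2 (-0.70 ± 0.071, edgeR adjusted p = 1.2e-05), KLK2 (-0.50, edgeR adjusted p = 0.0021), KLK3 (-0.49, edgeR adjusted p = 0.0056) and STEAP4 (-1.14). FKBP5 (-0.27) was not called by edgeR (adjusted p = 0.12). Of the 41 androgen-induced genes, 16 fell and 5 rose (19 and 5 adjusted over the list alone, median -0.27, camera adjusted p = 1.1e-04), and of 16 luminal genes 7 fell and CDH1 rose (7 and 1 adjusted over the list alone, median -0.14, camera adjusted p = 0.0063). ER chaperone and secretory genes fell in 15 of 24 cases, with EDEM1 at -0.68, XBP1 at -0.67 and HERPUD1 at -0.72, all parts of the unfolded protein response (16 adjusted over the list alone, median -0.39, camera adjusted p = 8.9e-11). Integrated stress genes fell in 15 of 28 cases, with the carboxykinase PCK2 at -0.88 (16 adjusted over the list alone, median -0.34, camera adjusted p = 4.6e-09), and sterol and fatty acid synthesis genes fell in 11 of 27 cases, with FASN at -0.92, while ELOVL6 rose (16 and 1 adjusted over the list alone, median -0.32, camera adjusted p = 1.2e-05). GDF15 (-1.53), AGR2 (-1.37) and S100P (-1.25) fell, and ACKR3 (1.59), CAMK2N1 (1.52), FAM184B (2.15) and EFNA5 (0.86) rose. Only 5 of 35 S phase and mitosis genes fell, FOXM1, E2F1, CCNB2, TK1 and AURKA (6 adjusted over the list alone, median -0.28, camera adjusted p = 6.1e-05). These genes had adjusted p = 0.39 with an estimated correlation. The neuronal REST targets were again not called (median -0.12, camera adjusted p = 0.23). The number of genes called was 1907, 779 higher and 1128 lower, with 332 higher and 449 lower in both treatments and 19 opposite. It fell to 1226 and 1268 without control replicate 1 or 3 in R1881 and to 1092 and 1131 without siRCOR1 replicate 2 or 3, and was 3192 with 1 surrogate variable and 3386 with the GC and length offset; with library size alone 67.7% of calls were higher instead of 40.8%.

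**Figure D5:**
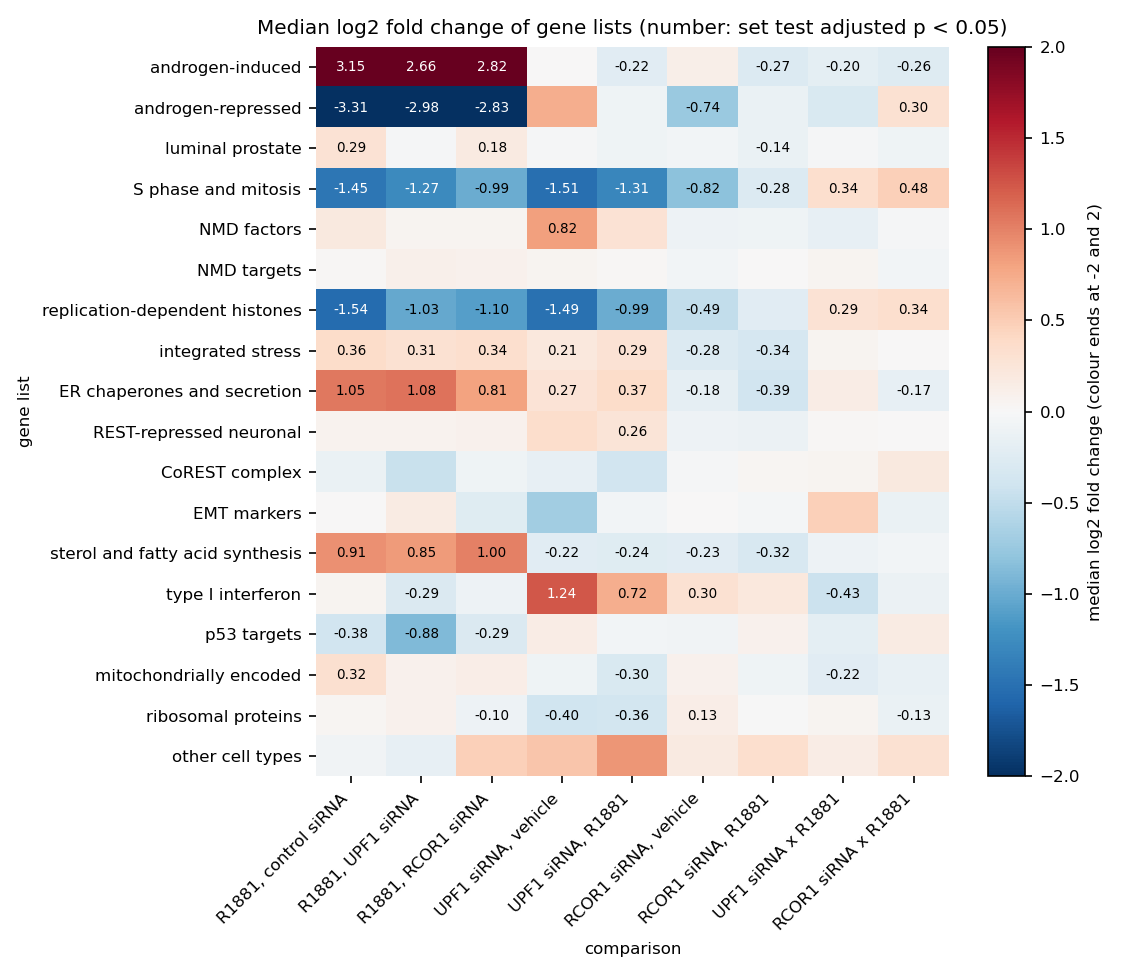
The colour gives the median log2 fold change of each of the 18 gene lists in each of the 9 comparisons, and a printed median marks a list called by camera at a preset correlation. Of the 72 marked fields, 27 were also called with an estimated correlation.

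The UPF1 interaction asks which genes answered R1881 differently when UPF1 was lowered. AGR2 is 1 example: it rose from 7.34 ± 0.41 to 42.5 ± 1.6 CPM with control siRNA, but stood at 54.3 ± 0.42 CPM without androgen and 65.6 ± 7.5 CPM with it when UPF1 was lowered. The stress cytokine GDF15 (189 ± 19 to 611 ± 66 CPM with control siRNA, 888 ± 190 to 978 ± 100 CPM with UPF1 siRNA) and the transcription factor KLF4 (13.4 ± 1.5 to 38.7 ± 1.3 CPM, against 58.8 ± 14 to 38.9 ± 3.7 CPM) also started higher, and KLF4 then fell. The androgen targets NDRG1 (interaction -1.48 ± 0.14), PLPP1 (-0.44 ± 0.088), ACSL3 (-1.29) and GNMT (-0.66) responded less, while KLK2 (0.69 ± 0.14) responded more, from a lower level in vehicle. The most positive interactions were SLITRK3 (2.28 ± 0.22), the ligand WNT5A (1.67 ± 0.25), EMP2 (1.42 ± 0.18), EME1 (1.37 ± 0.31), MEGF6 (1.37 ± 0.27) and the replication licensing factor CDC6 (1.33 ± 0.23). The most negative were SAMD9 (-3.41 ± 0.83), TTN (-3.38 ± 0.78), BIRC3 (-3.26 ± 0.61), ZNF292 (-3.25 ± 0.81), the angiopoietin ANGPT2 (-2.82 ± 0.49) and ARAP2 (-2.69 ± 0.63). With the GC and length offset these 6 were smaller in size, at -2.47, -1.96, -2.47, -2.2, -2.30 and -2.2. The offset does not separate GC content from length. Several of these 6 also varied widely between libraries of a group. With UPF1 siRNA in R1881, SAMD9 stood at 2.62 ± 1.88, TTN at 16.6 ± 7.49 and BIRC3 at 36.1 ± 28.5 CPM. There, ZNF292 stood at 6.11 ± 2.37, ANGPT2 at 6.89 ± 2.97 and ARAP2 at 11.3 ± 9.24 CPM. In vehicle with UPF1 siRNA, the spread was widest for SAMD9 (25.7 ± 17.4 CPM) and ZNF292 (62.5 ± 42.5 CPM). The androgen-induced list was lower (median -0.20; 2 higher and 4 lower, 2 and 10 adjusted over the list alone, camera adjusted p = 0.013), and S phase and mitosis genes, which R1881 lowered less, were higher in 11 of 35 cases (11 higher and 2 lower adjusted over the list alone, median 0.34, camera adjusted p = 1e-05). The S phase and mitosis list had adjusted p = 0.34 with an estimated correlation. In all, edgeR called 419 genes, 208 higher and 211 lower. Of the 341 that also answered R1881 with control siRNA, 280 had a smaller response with UPF1 siRNA and 61 a larger one; the control response enters both sides of that comparison.

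The count of the UPF1 interaction depended on single libraries. It was 222 and 264 without control replicates 2 and 3 in vehicle, 188 without UPF1 siRNA replicate 2 in vehicle, 815, 188 and 185 without control replicates 1, 2 and 3 in R1881, and 195, 209 and 1166 without UPF1 siRNA replicates 1, 2 and 3 in R1881. Without both AT-poor libraries of the last group it was 60. The balance of directions also changed: the share of higher calls was 49.6%, but 75.2% with library size alone, 17.2% of 1320 calls without a low-count filter and 29.3% of 1761 with 1 surrogate variable.

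The RCOR1 interaction asks the same for RCOR1. Prostate genes gained less: TMPRSS2 (interaction -0.82), KLK2 (-1.08), KLK3 (-0.85), the kinase SGK1 (-1.12), PLPP1 (-0.51), MAF (-0.59), PMEPA1 (-0.45) and SLC45A3 (-0.66) were lower and the channel gene TRPM8 (0.96) higher. GDF15 stood at 208 ± 27 CPM in vehicle and 212 ± 13 CPM in R1881 with RCOR1 siRNA, and AGR2 rose by a log2 fold change of 0.68, against 2.54 with control siRNA. The most positive interactions were SLITRK3 (1.76 ± 0.24), ACKR3 (1.49 ± 0.16), the apoptosis gene PMAIP1 (1.42 ± 0.3), TLL2 (1.2 ± 0.2), CDCA7 (1.14 ± 0.25) and VWF (1.08 ± 0.23), and the most negative AGR2 (-1.86 ± 0.15), the sodium channel subunit SCNN1G (-1.85 ± 0.28), KLF4 (-1.72 ± 0.19), GDF15 (-1.67 ± 0.2), TPM1-AS (-1.52 ± 0.25) and S100P (-1.36 ± 0.21). The androgen-induced list was lower (median -0.26; 8 lower and 1 higher, 14 and 1 adjusted over the list alone, camera adjusted p = 5e-11), and the androgen-repressed list was higher, with OPRK1 (0.85) and ACKR3 (median 0.30; 4 adjusted over the list alone, camera adjusted p = 3.9e-06). The repressed list had adjusted p = 0.13 with an estimated correlation. As a list, S phase and mitosis genes were higher with no member called over all genes (6 adjusted over the list alone, median 0.48, camera adjusted p = 5.8e-12). That list had adjusted p = 0.16 with an estimated correlation. The edgeR test called 118 genes, 35 higher and 83 lower. Of the 107 that also answered R1881 with control siRNA, 99 responded less and 8 more, by a comparison that uses the control response on both sides. Both interactions were higher in 10 genes and lower in 31, where independent lists would share 0.5 and 1.1, and opposite in AFF3 and KLK2. They use the same 6 control libraries, so part of this overlap may come from shared error: across genes, r was 0.32 with a covariance of 0.099, and simulated unchanged arms gave 0.50 and 0.08. Those arms had 0 shared calls, but almost no gene is called in arms without an effect, so that 0 is no reference. Draws from library residuals gave a mean covariance of 0.067 against 0.055 observed on that scale, and 51.3% of them were as large.

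The count of the RCOR1 interaction also changed when single libraries were left out. It was 57 and 60 without control replicates 1 and 3 in vehicle, 67 and 62 without RCOR1 siRNA replicates 1 and 2 in vehicle, 52, 50 and 58 without control replicates 1, 2 and 3 in R1881, and 51 and 58 without RCOR1 siRNA replicates 2 and 3 in R1881. The other runs gave 122 without control replicate 2 in vehicle, 93 without RCOR1 siRNA replicate 3 in vehicle and 80 without RCOR1 siRNA replicate 1 in R1881. Each run has 1 library fewer, so lost power and the part of a given library cannot be told apart. With library size alone 50.9% of calls were higher instead of 29.7%, and the count was 57.

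The 2 siRNAs shared part of their effects in vehicle. KLF4 (2.13 with UPF1 siRNA and 1.2 with RCOR1 siRNA), FBN1 (2.92 and 1.63), EPB41L3 (2.04 and 1.52), CRISP3 (1.87 and 1.57) and CAMK2N1 (0.99 and 1.09) rose with both, and TPX2 (-1.6 and -0.94), AURKA (-1.31 and -0.95) and SHCBP1 (-1.39 and -1.37) fell with both. Together, 414 genes rose with both siRNAs, where independent lists would share 151.5, and 489 fell with both, where they would share 153. Another 205 were called in opposite directions. The log2 fold changes correlated across genes (Pearson r 0.42, covariance 0.122), where genes are not independent replicates and both comparisons use the same 3 control libraries. Simulated unchanged groups set against shared controls gave a mean r of 0.50 with a covariance of 0.041, so that r alone was no larger than shared controls give. They had 0 shared calls, but almost no gene is called in groups without an effect. That 0 is therefore no reference for the shared calls observed. Draws from the residuals of the libraries, which keep the differences in AT-rich genes, gave a mean covariance of 0.034 and a highest of 0.179 against 0.09 observed on that scale, and 4.4% of 1000 draws were as large. The 3 control libraries do not give each siRNA 2 of its own, and no run with divided controls was made, so part of the overlap may come from the shared controls. Without RCOR1 siRNA replicate 2 in vehicle the number of genes called in the same direction was 587 instead of 903.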

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

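Of the tests in this part, the offset for GC content and length, the runs without pairs of libraries and the sorting of splits by whether the siRNA effect cancels were chosen only after the result was seen.

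The response to R1881 differed between UPF1 siRNA and control siRNA, by the interaction test, in 419 genes and in 5 lists. The list medians of the difference were -0.20 for androgen-induced genes, 0.34 for S phase and mitosis genes, 0.29 for replication-dependent histone genes, -0.43 for interferon-stimulated genes and -0.22 for mitochondrially encoded genes, with camera adjusted p = 0.013, 1e-05, 2.1e-06, 0.0016 and 0.017. All but the androgen-induced list lost the call with an estimated correlation (adjusted p = 0.34, 0.42, 0.23 and 0.57). Among the steepest positive differences (log2) were SLITRK3 at 2.28, WNT5A at 1.67, EMP2 at 1.42, EME1 and MEGF6 at 1.37 and CDC6 at 1.33. Among the steepest negative ones were SAMD9 at -3.41, TTN at -3.38, BIRC3 at -3.26, ZNF292 at -3.25, ANGPT2 at -2.82 and ARAP2 at -2.69. Several of these negative ones varied widely between libraries of a group, as given above. Among androgen targets, NDRG1 differed by -1.48, PLPP1 by -0.44 and KLK2 by 0.69. Androgen-repressed OPRK1 differed by 1.12 and DDC by 0.84, and the luminal genes ACP3 by -0.67 and STEAP1 by -0.87. The replication genes MCM3 and MCM7 and the mitotic cyclin gene CCNB1 differed by 0.79, 1.05 and 0.95, and the histone genes H2BC15, H2BC21 and H2BC12 by 1.10, 0.54 and 0.71. The NMD targets ATF3, SRSF2, MAP3K14 and SNHG8 differed by -0.69, 0.40, -0.77 and 0.56. Stress genes STC2, NUPR1, ERN1, XBP1 and PDIA4 differed by 0.66, -0.79, -0.56, -0.58 and 0.52. Other list members were FN1 at 0.63, SCD at -0.33, RSAD2 at -0.91, GDF15 at -1.56, TNFRSF10B at -0.41, ACTA2 at -1.50 and KRT14 at 1.44. Genes named in other comparisons were IL1RN at 1.32, RAET1L at -1.18, CLDN8 at -1.65, AGR2 at -2.26, TLL2 at 0.98, KLF4 at -2.12, TPM1-AS at -2.37 and S100P at -2.24. With the GC and length offset XBP1 (-0.33, edgeR adjusted p = 0.32) and RSAD2 (-0.70, edgeR adjusted p = 0.058) lost their calls.

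The response to R1881 differed between RCOR1 siRNA and control siRNA in 118 genes and in 6 lists. The list medians were -0.26 for androgen-induced genes, 0.30 for androgen-repressed genes, 0.48 for S phase and mitosis genes, 0.34 for replication-dependent histone genes, -0.17 for ER chaperone and secretory genes and -0.13 for ribosomal protein genes, with camera adjusted p = 5e-11, 3.9e-06, 5.8e-12, 2.8e-06, 2.3e-04 and 1.2e-05. All but the androgen-induced list lost the call with an estimated correlation (adjusted p = 0.13, 0.16, 0.42, 0.069 and 0.59). Genes with a positive difference were SLITRK3 at 1.76, ACKR3 at 1.49, PMAIP1 at 1.42, TLL2 at 1.2, CDCA7 at 1.14, VWF at 1.08 and OPRK1 at 0.85. Genes with a negative difference were AGR2 at -1.86, SCNN1G at -1.85, KLF4 at -1.72, GDF15 at -1.67, TPM1-AS at -1.52, S100P at -1.36, KRT19 at -1.25, SGK1 at -1.12, KLK2 at -1.08, KLK3 at -0.85, TMPRSS2 at -0.82, EFNA5 at -0.62, XBP1 at -0.60, HERPUD1 at -0.52 and PLPP1 at -0.51. With the GC and length offset XBP1 (-0.67, edgeR adjusted p = 0.097) lost its call.

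The log2 differences of the UPF1 interaction rose with GC content over 10413 protein-coding genes, called or not, with a Spearman rho of 0.52 across genes, which are not independent replicates. An offset for GC content and length removed the trend, with a rho of -0.07. After it, 91.6% of the called genes were still called, which argues against the trend as the whole cause of those calls. That fit called 2011 genes in all against 419, so more genes passed under it. The share therefore cannot tell how far the trend contributed to each difference. The trend itself may come from the 2 libraries with UPF1 siRNA and R1881 that are lowest in AT-rich genes: without them rho was 0.19 and 60 genes were called. A sharper decline of AT-rich transcripts caused by UPF1 siRNA with androgen stays open, as the third library of that group did not show it and 1 library cannot decide.

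The androgen-induced list gained less from R1881 with RCOR1 siRNA, by a median of -0.26. GC content and length are argued against, since the median was -0.34 with the offset and the list was called with the preset and the estimated correlation. A direct part of RCOR1 in the transcription of these genes stays open, as it was not tested.

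The NMD target list showed no net change with UPF1 siRNA in vehicle, although UPF1 stood at 17% of control. GC content and length are argued against as a mask, since the median was 0.07 with the offset and 0.05 without it. A mixture of decay-prone and stable isoforms in the count of each gene stays open: the test took 31 genes whose longest coding transcript has an exon junction over 50 nt past the stop codon, which lay -0.11 from genes matched for expression and GC content (2-sided permutation test, p = 0.21, spread of matched draws 0.09). This met the bound set beforehand against this explanation (a difference below 0.05). Yet 0 of the 35 listed targets were among these genes, and the demand that they be was added after the result was seen. Only transcripts annotated as protein-coding were used, so decay-prone isoforms with another annotation were left out. The test therefore cannot decide. The remaining UPF1 could also sustain decay, which was not tested.

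Other splits of the libraries bear on the counts of called genes. For the UPF1 interaction, 11 of 100 splits, the real one included, called at least 419 genes, with 3776 as the highest of the others, and for the RCOR1 interaction 12 of 100 called at least 118, with 742 as the highest, so that these splits cannot exclude chance. Splits with many calls point to a structure of the libraries: all 10 others for UPF1 and all 11 for RCOR1 carried part of the siRNA effect into the interaction. Among the 40 splits of each in which that effect cancels, 0 called as many by edgeR and the highest count was 0. Those splits put libraries of both siRNAs into the same group, so the siRNA effect widens the spread within groups. Few calls could come of them, and their counts cannot decide. For the other comparisons, 3 libraries against 3 give 10 splits, too few for a share below 0.05. In each, 1 split, the real one, called as many. The other splits again mix both conditions within groups, so their low counts cannot decide either. The real count and the highest other were 5801 and 0 for R1881 with control siRNA, 6405 and 308 with UPF1 siRNA, 4796 and 0 with RCOR1 siRNA, 5318 and 0 for UPF1 siRNA in vehicle, 5128 and 1214 in R1881, 1772 and 0 for RCOR1 siRNA in vehicle, and 1907 and 0 in R1881.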

How the results depend on the processing

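The GC and length offset, the replicate block, the runs without pairs of libraries and the surrogate variable for lists, sizes and overlap were chosen only after the result was seen; all others were set before. The labels give no replicate numbers. With the order of the titles as a replicate block, the interactions gave 798 and 186 genes and the other counts stayed within 1.5 times. That order is no stated pairing: libraries with the same place correlated between -0.48 and 0.48, with 30 of 45 pairs above 0.1, and 11 of 18 were closest to their own. The negative values lay in the second place or in pairs with the first library of control siRNA in vehicle. A shared preparation of some libraries by place therefore stays possible and was not tested. Over the settings chosen beforehand, named genes kept their direction and side of the threshold in 7432 cases, lost the call in 568, gained it in 15 and reversed in 2; over the added ones the counts were 1087, 111, 17 and 1. List calls held in 644 and were lost in 70 cases of the former, and held in 140 and were lost in 4 of the latter. The reversals were RPL7L1 (-0.061) and RPL38 (-0.005) in the androgen response with control siRNA under library size alone, which lowers all genes, and MT-ND4L (0.223) with UPF1 siRNA in R1881 under the offset.

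Main counts within 1.5 times of the value given above are left out here. With only the groups compared in the fit, which leaves fewer libraries for the dispersion, the count was 744 for RCOR1 siRNA in vehicle, 745 in R1881, 177 for the UPF1 interaction, 27 for the RCOR1 interaction and 383 for the overlap. With 1 surrogate variable these were 2855, 3192, 1761, 258 and 1509, and with the offset 3639, 3386, 2011, 525 and 1905. Both adjust for differences between libraries, but why the counts rose was not tested. The UPF1 interaction gave 1320 without a low-count filter, and the RCOR1 interaction 57 with library size alone; the cause was not tested. With both AT-poor libraries of UPF1 siRNA in R1881 left out, which leaves 1 library assumed to vary like the other groups, counts were 2924 for the androgen response with UPF1 siRNA, 1904 for UPF1 siRNA in R1881 and 60 for the UPF1 interaction, and the slopes were 0.859 for UPF1 and 0.842 for RCOR1. Without 2 control libraries the interactions gave 263 and 60 and both slopes were 0.783. The RCOR1 slope was 0.791 without a filter and 0.794 with genes called in either arm, and the UPF1 slope was 0.82 with the latter. With an estimated correlation 27 list calls held. Without 5 genes that do not belong to the histone class, also a run added afterwards, the medians of the other 44 were -1.68 for R1881 with control siRNA, -1.54 for UPF1 siRNA and -0.53 for RCOR1 siRNA in vehicle, and no call of that list changed.

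Leaving out 1 library at a time gave 4889 to 5416 genes for R1881 with control siRNA, 4876 to 6779 with UPF1 siRNA, 3835 to 4662 with RCOR1 siRNA, 4407 to 4701 for UPF1 siRNA in vehicle and 3762 to 5441 in R1881, 1118 to 1443 for RCOR1 siRNA in vehicle and 1092 to 1425 in R1881, 185 to 1166 for the UPF1 interaction, 50 to 122 for the RCOR1 interaction, 71 to 78 list calls, 587 to 855 shared calls, and slopes of 0.782 to 0.834 for UPF1 and 0.787 to 0.841 for RCOR1. UPF1 moved from -2.66 to -2.45 in vehicle and -2.58 to -2.42 in R1881, and RCOR1 from -3.14 to -2.76 and -2.76 to -2.62. In simulated counts, small changes were found less often in interactions than in simple comparisons. Of changes of 1.5-fold set there, 6% were found in the UPF1 interaction and 9% in the RCOR1 interaction, against 38.8% for R1881 with control siRNA.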

Other observations

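The tests on 3' UTR length and on the composition of libraries were added after the data were seen, with their criteria written before their results, except the correlation of the surrogate variable, which had none.

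KLF4 rose with R1881 from 13.4 ± 1.5 to 38.7 ± 1.3 CPM with control siRNA, but stood at 58.8 ± 14 CPM in vehicle with UPF1 siRNA and at 30.9 ± 2 CPM with RCOR1 siRNA. S100P, a calcium-binding protein, rose from 4.94 ± 0.86 to 22.8 ± 0.27 CPM with control siRNA, stood at 22.3 ± 3.3 CPM in vehicle and 21.8 ± 3.1 CPM in R1881 with UPF1 siRNA, and at 5.31 ± 0.53 and 9.56 ± 1 CPM with RCOR1 siRNA. The interactions of KLF4, S100P, AGR2, GDF15 and TPM1-AS were negative for both siRNAs, and SLITRK3 and TLL2 were positive for both, where both use the same control libraries and like signs may come from shared error. These genes were picked after their values were seen.

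UPF1 binds long 3' UTRs, so genes with long 3' UTRs could rise when UPF1 is lowered. Among 10260 protein-coding genes with an annotated 3' UTR (98.5% of those tested), the 2565 with the longest (above 2417 nt) were set against the 2567 with the shortest (below 409 nt). After the GC and length offset the medians differed by 0.05 log2 units in vehicle (2-sided permutation test over genes, p = 0.0003) and by 0.14 in R1881 (p = 1e-05, the smallest these permutations can give). Without the offset the same permutation test gave differences of 0.12 (p = 1e-05) and -0.05 (p = 0.0013), so the direction in R1881 depended on the offset. With RCOR1 siRNA in vehicle the difference was 0.00 (permutation p = 0.96). With the offset, the value in vehicle lies below the 0.10 set beforehand for this hypothesis and at its lower bound of 0.05. However, the offset was fitted per library on transcript length, which includes the 3' UTR, without regard to group. It may have removed part of the effect sought, so this value cannot decide. The values without it do not allow for GC content. The hypothesis stays undecided, and genes are not independent replicates.

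The RCOR1 interaction was negatively related to GC content across genes (rho -0.40). With 1 surrogate variable rho fell to -0.14. Among the comparisons that make up the interaction, rho shrank for R1881 with RCOR1 siRNA (-0.304 to -0.07) and with control siRNA (-0.059 to 0.009) and grew for RCOR1 siRNA in vehicle (0.042 to -0.266) and in R1881 (-0.321 to -0.385). The UPF1 interaction kept 0.412 of 0.523. A difference in library composition that runs through all groups is a candidate source, which these values do not settle. That variable itself followed the level of AT-rich genes over the 18 libraries (Pearson r 0.79, permutation p = 0.0002, Spearman rho 0.7, permutation p = 0.0016). Without the 2 libraries farthest from the median of that level these were 0.71 (permutation p = 0.0029) and 0.62 (permutation p = 0.013). Both measures were taken from the same counts, in which the within-group differences already followed GC content. The relation is therefore in part built in, and these p give no independent support.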
